A study of Mus musculus with 12 samples.

How the data were processed

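Messenger RNA was sequenced from mouse bone marrow-derived macrophages, cells grown from the marrow of C57BL/6 mice for 7 to 8 days in medium conditioned by L929 cells, a source of the growth factor M-CSF. Per the labels, the mice were wild type (WT) or lacked the histone methyltransferase DOT1L in myeloid cells (KO), with Lyz2 named as the myeloid gene of the strain, and the cells were left untreated or given 10 ng/mL of lipopolysaccharide (LPS) from Escherichia coli for 3 hours. Each of the 4 groups held 3 libraries that the labels call biological replicates. Per the labels' protocols, 700 ng of RNA from 500000 cells was made into libraries with a poly(A) mRNA kit and sequenced single-end at 50 bp, with about 20 M reads planned per library.

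The deposited tables give whole-number read counts and RPKM values for 35745 RefSeq transcripts, in 1 pair of tables for the untreated libraries and 1 pair for the LPS-treated libraries. The submitters' processing notes name STAR 2.5.2b, SAMtools 1.3.1 and the mm10 build, while the counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited counts are not normalized, and reads that lie in several isoforms appear once for each isoform: in the 3305 genes with several transcripts and 1000 reads, the lowest transcript held a median of 97.9% of the reads of the highest. The authors' RPKM values divide the counts by transcript length and by 1 constant per library, and served as an alternative only.

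Each gene was therefore represented by its transcript with the highest total count, which gave 24445 genes, of which 6089 had several transcripts. Gene names came from a RefSeq table of GRCm38.p6, the same assembly as mm10, for 35435 transcripts and from GENCODE for 193 more. The other 117 transcripts had no name, took 0.259% to 0.738% of the counts of a library and were left out. Total counts over 1 transcript per gene ran from 8.64 to 13.54 M (1e6) per library. A floor of 3 counts corresponds to 0.222 to 0.347 counts per 1e6 counts (CPM), and intervals and floors cover counting error only.

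Genotypes were compared separately without and with LPS, on the 6 libraries of each condition, because the submitters kept the conditions in separate tables. The LPS response of each genotype and the genotype by LPS interaction were fitted on all 12 libraries as 4 groups. Genes passed edgeR's filterByExpr, libraries were scaled by TMM, and edgeR's quasi-likelihood F test with robust dispersions was used with Benjamini-Hochberg adjustment and a threshold of 0.05 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, R 4.3.3). All adjusted p of single genes come from that test unless another tool is named. Values after ± are approximate standard errors of log2 fold changes with 3 libraries per group, unless called SD. They were derived from the test, as the size of the change over the square root of its F statistic. They thus hold a spread moderated over all genes, and, in fits of all 12 libraries, a spread over all of these. With 3 libraries against 3, an exact permutation test of 1 gene cannot give a two-sided p under 0.1, so none was used. Folds of genes with 10 or fewer reads in all libraries of a group are ratios of pooled CPM with exact binomial 95% intervals, or, at 0 reads, lower bounds against the floor of 3 counts over the group.

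Before the data were examined, 30 gene lists were fixed: cholesterol synthesis, fatty acid synthesis, LXR targets and efflux, lipid uptake and storage, fatty acid oxidation, inflammatory cytokines, chemokines, interferon response, the TLR4 and NF-kB pathway, negative feedback, alternative activation, macrophage identity, antigen presentation, cell cycle, DOT1L partners, the HOXA and MEIS genes, matrix remodelling, glycolysis and hypoxia, ATF4 stress, NRF2 and oxidative stress, early stress, sex genes, and markers of neutrophils, mast cells and basophils, dendritic cells, lymphocytes, stromal cells, erythroid cells and megakaryocytes, osteoclasts, and monocytes. Lists with at least 5 measured members, the sex genes left out, were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. No list was chosen on these libraries.

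The genes named for each genotype comparison were set by a rule fixed before the data were examined: Dot1l, the 6 called genes with the largest change in each direction at a mean log2 CPM of at least 2 and with no overlap between groups, up to 4 called members of each list by smallest p, and the most highly expressed member of a list without calls. Predicted genes, pseudogenes and sex genes were left out of the largest changes. The interaction followed the same rule, and the LPS comparisons took 3 members per list. Cd74 with LPS and the genes named in the closing section alone lie outside the rule and were chosen after their values were seen. Some genes that the rule or a test takes are not reported here by name.

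Replicates were checked for repeats by a chi-square of their counts per degree of freedom, which lay between 2.54 and 32.4, so no pair of libraries agreed within sampling noise. The labels do not say that a replicate number links libraries. In the data, the deviations from the group means of the untreated and the LPS-treated library with the same number correlated in WT (0.57, 0.56 and 0.30) and in KO (0.25, 0.45 and 0.20), all above the minimum of 0.1 set beforehand, so within a genotype the numbers were taken to pair the libraries. Untreated libraries of different genotypes with the same number also passed this minimum for replicate 2 (0.18) and replicate 3 (0.26), but not for replicate 1 (0.05). The minimum therefore does not show that libraries share an animal, and the pairing is an assumption. Xist and the Y-linked genes gave replicate 2 of all 4 groups as male and the others as female.

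The test was tried on simulated counts drawn from the real means and library sizes with 200 changed genes. Of genes changed 2-fold and 1.5-fold, edgeR called 80% and 36% for KO against WT without LPS (11622 genes), 89% and 47% with LPS (11264 genes), 83% and 39% for LPS in WT, 79% and 31% for LPS in KO, and 58% and 4% for the interaction (11984 genes each). Unchanged genes made up 12.8%, 6.8%, 6.2%, 5.2% and 7.5% of the respective calls. Camera called the raised simulated list and 0 of 20 unchanged lists in each of the 5 comparisons. The simulated genes were drawn independently of each other, whereas real lists had estimated correlations of up to 0.72 (cholesterol synthesis, KO against WT without LPS). The trial therefore does not show how often camera calls unchanged lists whose genes move together. No simulated library stood apart over many genes at once, as WT replicate 1 did in the data. The shares of changed genes called may therefore not hold for the real libraries, and 0 calls there do not show that few genes changed.

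Alternatives fixed beforehand were other scalings (DESeq2 size factors, upper quartile), DESeq2, limma-voom, limma-trend on log2(RPKM + 0.5), other filters on low counts, thinning to the smallest library, other thresholds, replicate blocks, other sets of libraries and leaving out each library in turn. Sex as a covariate, female libraries only, leaving out both WT replicate 1 libraries, every transcript in place of 1 per gene, and blocks in the list tests of the LPS comparisons and the interaction were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.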

Results

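The series concerns DOT1L, a histone methyltransferase, and its part in lipid synthesis and inflammatory responses of macrophages. Messenger RNA of bone marrow-derived macrophages was measured in 12 libraries: 3 each of untreated WT, untreated KO, LPS-treated WT and LPS-treated KO cells. LPS is a bacterial cell wall component that activates the receptor TLR4. Replicates 1, 2 and 3 held 8.98, 11.76 and 11.13 M (1e6) counts in untreated WT, 12.89, 10.58 and 12.21 M in untreated KO, 8.64, 11.91 and 10.38 M in LPS-treated WT, and 13.54, 13.46 and 12.75 M in LPS-treated KO. The 10 most abundant genes took 10.5% to 12.1% of the counts of a library. Replicate 2 was male in all 4 groups, with Xist at 0.168 to 0.52 CPM, Ddx3y at 76.4 to 128 CPM, Eif2s3y at 41.8 to 75.1 CPM, Kdm5d at 20.3 to 39.4 CPM and Uty at 23.7 to 48.9 CPM. The other libraries had Xist at 453 to 1026 CPM and each Y-linked gene at no more than 0.09 CPM, so sex was balanced between the genotypes.

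The first principal component, with 85.6% of the variance, parted LPS-treated from untreated libraries. WT replicate 1 stood apart in both conditions: it lay at 36.1 untreated and 35.6 with LPS on the second component (4.4% of the variance), where the other 10 libraries lay between -12.9 and 3.6. Its distance to its group mates was 0.50 and 0.463 (root mean square of log2 differences), against 0.248 to 0.411 in the others. Cholesterol synthesis genes were lower in this replicate, with a mean log2 CPM of 5.28 against 6.19 and 6.05 in the other untreated WT libraries and of 5.20 against 5.99 and 5.80 with LPS. The effect of leaving it out is given with each comparison it changes.

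Dot1l itself (chromosome 10, 80755101 to 80795461, mm10) did not differ between genotypes by the test, with CPM scaled within each condition and so not comparable between conditions. Untreated cells had 122.6 ± 19.6 CPM in WT and 110.5 ± 8.75 CPM in KO (SD, n = 3 each), a log2 fold change of -0.15 ± 0.13 (adjusted p = 0.902). With LPS the levels were 54.1 ± 3.28 and 57.0 ± 3.70 CPM (SD, n = 3 each), a log2 fold change of 0.07 ± 0.09 (adjusted p = 0.754). Without untreated WT replicate 1, the first of these became -0.28 and passed the threshold (adjusted p = 0.0244). Counts cover the whole transcript and the deleted exons are not given in the sources used here, so these reads check nothing about the labels. Lyz2 (lysozyme; chromosome 10, 117277541 to 117282272), the myeloid gene named in the labels, separated the genotypes instead. Untreated cells had 7563 ± 1031 CPM in WT and 3387 ± 271.8 CPM in KO, and LPS-treated cells had 5769 ± 716.5 and 2564 ± 195.7 CPM (SD, n = 3 each). The log2 fold change of Lyz2 was -1.16 ± 0.11 without LPS, which missed the threshold (adjusted p = 0.0784), and -1.17 ± 0.10 with LPS, which passed it (adjusted p = 0.00143). Without untreated WT replicate 1, Lyz2 passed without LPS too, at -1.04 (adjusted p = 6.74e-08). On 1 common scale, the highest KO library had 0.529 of the lowest WT library's Lyz2 without LPS and 0.537 with LPS.

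**Figure D1:**
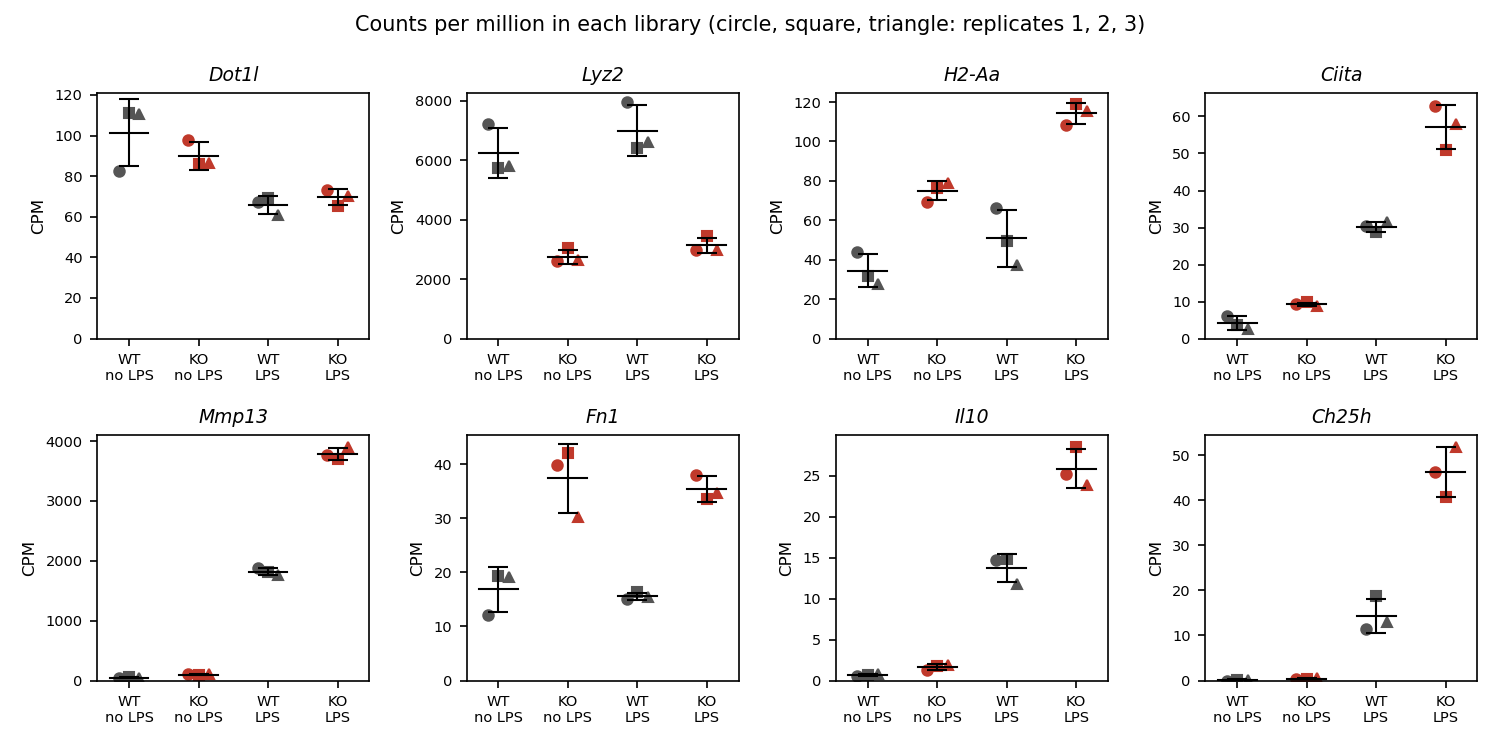
CPM (vertical axes, from 0) of 8 genes in the 12 libraries, scaled together, with WT in grey and KO in red, a symbol per replicate, a bar for the mean and whiskers for the SD of 3 libraries. Dot1l overlaps between genotypes (82.4 to 111.2 CPM in WT and 85.8 to 97.8 CPM in KO, untreated), whereas the highest KO library of Lyz2 has 0.529 and 0.537 of the lowest WT library.

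KO was first compared with WT in untreated cells, the comparison of resting macrophages. Of 13 genes of antigen presentation, 12 were higher in KO, with a median log2 fold change of 0.58 and 0 single genes called (list adjusted p = 2.57e-11, and adjusted p = 0.353 with an estimated correlation). Their most abundant member, Cd74, the chaperone of MHC class II molecules, differed by 1.09 ± 0.23 and missed the threshold alone (adjusted p = 0.326). Interferon response genes were higher in 40 of 41 cases, with a median of 0.44 and 0 called (4.27e-13, and adjusted p = 0.621 with an estimated correlation). That median was 0.24, with 32 of 41 higher, without untreated WT replicate 3, and 0.28 without KO replicate 3. Markers of monocytes, the precursors of macrophages, were higher in 6 of 6, with a median of 0.60 (7.76e-04, and adjusted p = 0.353 with an estimated correlation) that ran from 0.40 without untreated WT replicate 2 to 0.97 without WT replicate 1. Genes of the NRF2 oxidative stress response were lower in 14 of 16, with a median of -0.17 (0.00246, and adjusted p = 0.377 with an estimated correlation). Partners of DOT1L in transcription elongation were lower in 15 of 16, with a median of -0.10 (0.00458, and adjusted p = 0.621 with an estimated correlation), which was -0.03, with 7 of 16 higher, without untreated WT replicate 1 and -0.18 without WT replicate 2.

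These 5 of 23 lists passed camera with its preset correlation, and 0 did with an estimated correlation. Adjusted over the list alone, 8 antigen presentation genes and 1 monocyte marker rose, 1 DOT1L partner fell, and 0 genes of the interferon and NRF2 lists passed. Such genes were not particular to called lists. Alternative activation had 3 higher and 1 lower, matrix remodelling 2 higher and 1 lower, and inflammatory cytokines 2 higher. LXR targets and the TLR4 pathway had 1 higher each, macrophage identity 1 higher and 1 lower, and osteoclast markers 1 lower. The most abundant members of the other called lists were Parp14 of the interferon response (0.17 ± 0.20, adjusted p = 0.938), Ccr2, a chemokine receptor of monocytes (0.41 ± 0.35, adjusted p = 0.904), Fth1, the ferritin heavy chain (-0.36 ± 0.12, adjusted p = 0.549), and the elongation factor Aff4 (-0.02 ± 0.10, adjusted p = 0.99). The NRF2 call was lost without untreated WT replicate 3 (adjusted p = 0.0709) and that of the DOT1L partners without untreated WT replicate 1 (adjusted p = 0.189).

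Lipid genes did not pass in untreated cells. Of 27 cholesterol synthesis genes, 21 were lower in KO (median -0.10, adjusted p = 0.649), and Hmgcs1, an early enzyme of the pathway, differed by -0.10 ± 0.16 (adjusted p = 0.958). Of 20 fatty acid synthesis genes, 15 were lower (median -0.07, adjusted p = 0.0896), with the desaturase Scd2 at -0.24 ± 0.09 (adjusted p = 0.606). LXR targets, which serve cholesterol efflux, were higher in 7 of 13 (adjusted p = 0.186), with the lipoprotein Apoe at 0.26 ± 0.24 (adjusted p = 0.91). Without untreated WT replicate 1, the library low in cholesterol synthesis genes, all 3 lists passed: cholesterol synthesis lower (adjusted p = 2.68e-11, range over the 6 fits without 1 library 2.68e-11 to 0.721), fatty acid synthesis lower (9.27e-04, range 9.27e-04 to 0.697) and LXR targets higher (4.76e-05, range 4.76e-05 to 0.649). Their medians in that fit were -0.33, -0.15 and 0.31. The cholesterol list turned with the libraries used: camera placed it on the higher side without untreated WT replicate 2 (adjusted p = 0.168, 21 of 27 genes higher, median 0.11), WT replicate 3 (0.532) or KO replicate 2 (0.721), and it passed as higher in the female libraries (adjusted p = 0.00662, and adjusted p = 0.95 with an estimated correlation). Fatty acid synthesis also passed without untreated KO replicate 1 (adjusted p = 0.0392) or 3 (adjusted p = 0.0436). Without untreated WT replicate 2 its tally turned, with 12 of 21 genes higher and a median of 0.03 (adjusted p = 0.697). The remaining 15 lists, which hold lipid uptake and storage, fatty acid oxidation, inflammatory cytokines, chemokines, the TLR4 pathway, negative feedback, alternative activation, macrophage identity, cell cycle, matrix remodelling, glycolysis, ATF4 stress, early stress, and neutrophil and osteoclast markers, had adjusted p between 0.126 and 0.882. Of these, 5 passed without untreated WT replicate 1: chemokines (0.0458) and negative feedback (0.0257) and cell cycle (9.94e-07) as lower, and macrophage identity (5.56e-04) and neutrophil markers (0.00207) as higher. Inflammatory cytokines passed as higher without untreated KO replicate 2 (0.0109), and alternative activation without KO replicate 3 (0.0452). In the female libraries cytokines (0.0245) and the cell cycle (0.0198) passed as higher (adjusted p = 0.732 and 0.936 with an estimated correlation). None of the 12 list calls gained without 1 library passed with an estimated correlation, where the smallest adjusted p was 0.43. The TLR4 list had a median of 0.01 while camera placed it on the lower side. Examples were the cytokine antagonist Il1rn (-0.19 ± 0.10), the chemokine Ccl9 (0.11 ± 0.08), the LPS receptor Tlr4 (0.06 ± 0.09) and the proliferation marker Mki67 (-0.18 ± 0.15), with adjusted p between 0.786 and 0.945. Lists too small for the test had 0 called genes: 4 measured HOXA and MEIS genes, 3 dendritic cell markers, 2 each for mast cells, lymphocytes and stromal cells, and 1 for erythroid cells and megakaryocytes.

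No single gene of the 11622 tested passed in edgeR, where the smallest adjusted p was 0.0784. At an unadjusted p under 0.05 there were 841 genes, DESeq2 called 49 and limma-voom 0, and the groups did not overlap for 14.7% of genes where random groupings give 10% on average. Without untreated WT replicate 1, edgeR called 749 genes, among them Cd74 (1.43), Hmgcs1 (-0.28), Ccr2 (0.97) and Fth1 (-0.21), each with an adjusted p of at most 0.0315, the value of Ccr2.

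With LPS, 127 single genes differed between KO and WT. Among genes at a mean log2 CPM of at least 2, the largest increases were those of Steap4, a metalloreductase (log2 fold change 2.03 ± 0.27), the leukocyte receptor Slamf1 (1.81 ± 0.17), Ch25h, the enzyme that makes an oxysterol from cholesterol (1.66 ± 0.17), the glycosyltransferase B3gnt7 (1.54 ± 0.17) and the carbonic anhydrase Car2 (1.53 ± 0.22). A larger value, 2.16 ± 0.20, was that of Mir5107 (chromosome 18, 60812076 to 60812163), a microRNA gene within the span of Cd74 (60803849 to 60812652), so its reads cannot be told from those of Cd74. Cd74 itself differed by 1.01 ± 0.25 and missed the threshold (adjusted p = 0.113). The largest decreases were those of Tox2, a nuclear factor (-1.20 ± 0.19), and Lyz2 (-1.17 ± 0.10), followed by Dipk2a (-0.70 ± 0.14), Arap2 (-0.68 ± 0.12), Fblim1 (-0.61 ± 0.09) and Dapk1 (-0.60 ± 0.12). Lyz2 is the myeloid gene that the labels name for the strain, so its decrease is not shown to follow from the loss of DOT1L. Adjusted p ran from 0.00143 to 0.00874 for the increases and from 0.00143 to 0.0422 for the decreases.

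In LPS-treated cells, the MHC class II genes H2-Aa and H2-Eb1 were higher in KO than in WT, by 1.17 ± 0.16 (adjusted p = 0.00874) and 0.99 ± 0.20 (adjusted p = 0.0472). So was Ciita, the activator of class II transcription, by 0.91 ± 0.11 (adjusted p = 0.00362). They were the 3 called of 13 antigen presentation genes, of which 11 were higher (median 0.50), and 11 rose when adjusted over the list alone. In this comparison "rose" and "fell" stand for higher and lower in KO than in WT, not for a change with LPS. Without LPS, H2-Aa differed by a similar 1.15 ± 0.16 (adjusted p = 0.156). The antigen presentation list did not pass camera in the interaction (adjusted p = 0.616). The lists called with LPS, this one among them, did not pass with an estimated correlation (adjusted p = 0.23 to 0.533). Among inflammatory cytokines, 19 of 25 were higher (median 0.24, and 0.46 without KO replicate 2 and 0.16 without KO replicate 3) and 2 rose, the anti-inflammatory Il10 (0.90 ± 0.13, adjusted p = 0.00874) and Il12a, a subunit of IL-12 (1.20 ± 0.21, adjusted p = 0.0276), with 10 adjusted over the list alone. The chemokines Cxcl3 (0.91 ± 0.17, adjusted p = 0.0385) and Ccl24 (1.28 ± 0.24, adjusted p = 0.0392) rose as 2 of 19 members of a list that did not pass as a whole (adjusted p = 0.134; 0.00235 without KO replicate 2, range 0.00235 to 0.474). Of 25 matrix remodelling genes, 5 rose, among them the collagenases Mmp13 (1.05 ± 0.08, adjusted p = 4.91e-04) and Mmp8 (0.71 ± 0.15, adjusted p = 0.0473), the fibronectin gene Fn1 (1.18 ± 0.11, adjusted p = 0.00143), and the inhibitor of matrix proteases Timp1 (1.16 ± 0.18, adjusted p = 0.0128). Adjusted over the list alone, 10 matrix genes rose and 1 fell. Ciita and Timp1 overlap the genes Dexi and Syn1, and the strand setting of the counts is not known.

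Markers of other cell types moved with the genotype as well. Of 11 dendritic cell markers 6 passed the filter on low counts, and all 6 were higher in KO (median 0.79). Cd24a, which macrophages express too, rose (1.17 ± 0.17, adjusted p = 0.00874). The filter left 5 markers without KO replicate 2 or 3, but 6 without any 1 WT library. A marker can thus enter through its level in KO, which favours a higher value there. Of 8 monocyte markers, 7 were higher (median 0.45) and 2 rose, Vcan (0.51 ± 0.10, adjusted p = 0.0407) and Fn1, which the matrix list also holds. Single members rose in lists that did not pass or were too small to test: Mmp8 of 6 neutrophil markers, Acp5 of 7 osteoclast markers (0.98 ± 0.10), Lck of 3 lymphocyte markers (0.68 ± 0.12) and Ppbp, the only measured platelet gene (2.11 ± 0.43). So did Clec10a, a lectin of alternatively activated macrophages (0.96 ± 0.17), the stress gene Ier3 (0.60 ± 0.09) and Elovl6, an enzyme of fatty acid elongation (0.70 ± 0.13), with adjusted p from 0.00186 to 0.0473 for these 7 genes. Interferon response genes were higher in 35 of 42, though with a median of 0.06, and Ifi44 rose (0.55 ± 0.11, adjusted p = 0.0471; list adjusted p = 0.533 with an estimated correlation). This tally depended on single libraries: 41 were higher without WT replicate 1 (median 0.16) and 36 without KO replicate 1 (0.10), but 24 without WT replicate 2 (0.03), 26 without WT replicate 3 (0.03) and 27 without KO replicate 2 (0.02). NRF2 genes were lower in 13 of 15 (median -0.22), with 0 called and 5 lower when adjusted over the list alone. DOT1L partners were lower in 12 of 16 (median -0.16, and -0.06 without WT replicate 1) and lipid uptake and storage genes in 15 of 23 (median -0.15, and -0.09 without WT replicate 3 and -0.10 without KO replicate 2), with 0 called in each.

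These lists were the 9 of 24 that camera called, 6 higher and 3 lower. The adjusted p was 1.58e-09 for antigen presentation, 2.38e-04 for NRF2, 3.24e-04 for dendritic cell markers and 5.62e-04 for monocyte markers (adjusted p = 0.23 with an estimated correlation, each). It was 2.64e-05 for cytokines (adjusted p = 0.331 with an estimated correlation), 3.24e-04 for matrix remodelling (adjusted p = 0.238 with an estimated correlation) and 3.24e-04 for the interferon response (adjusted p = 0.533 with an estimated correlation). It was 0.0208 for DOT1L partners (adjusted p = 0.533 with an estimated correlation) and 0.029 for lipid uptake (adjusted p = 0.231 with an estimated correlation). Fry called the dendritic cell markers and matrix remodelling. Lists without a call also had genes that passed when adjusted over the list alone, among them 4 higher and 2 lower of alternative activation and 3 higher and 1 lower of chemokines. The call of the DOT1L partners was lost without LPS-treated WT replicate 1 (adjusted p = 0.20) or KO replicate 3 (adjusted p = 0.055), and that of lipid uptake without WT replicate 3 (adjusted p = 0.11) or KO replicate 3 (adjusted p = 0.0529). In the female libraries the calls of the interferon response (adjusted p = 0.106) and lipid uptake (adjusted p = 0.0579) were lost, while chemokines (0.00766) and cholesterol synthesis (6.04e-04) passed as higher (adjusted p = 0.421 and 0.851 with an estimated correlation). The dendritic cell markers had too few measured members there to be tested.

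Lipid synthesis genes did not pass as lists with LPS either. Cholesterol synthesis genes had a median of -0.01 while camera placed them on the higher side (adjusted p = 0.422), and 0 of 27 were called. The list turned with the library left out: it was lower in KO without WT replicate 1 (median -0.18, adjusted p = 2.11e-04) and higher without WT replicate 2 (median 0.12, adjusted p = 0.00759), in a range of 2.11e-04 to 0.902. Fatty acid synthesis genes were lower in 17 of 22 (adjusted p = 0.164), and passed without WT replicate 1 (adjusted p = 0.0247) or KO replicate 1 (adjusted p = 0.0178). LXR targets were lower in 9 of 13 (median -0.06, adjusted p = 0.399), with Apoe at 0.09 ± 0.18. Without WT replicate 1 camera placed them on the higher side (adjusted p = 0.416, 8 of 13 higher, median 0.05), and without WT replicate 3 the median was -0.17. The other lists without a call, fatty acid oxidation, the TLR4 pathway, negative feedback, alternative activation, macrophage identity, cell cycle, glycolysis, ATF4 stress, early stress, and neutrophil and osteoclast markers, had adjusted p between 0.104 and 0.888. Without WT replicate 1, negative feedback (0.00385), glycolysis (0.0239) and neutrophil markers (0.00181) passed as higher and the cell cycle (5.37e-04) as lower, and glycolysis also passed without KO replicate 1 (0.0342). None of the 10 list calls gained without 1 library with LPS passed with an estimated correlation, where the smallest adjusted p was 0.197. In the osteoclast list the median (-0.13) and the direction of the test (higher) differed. The TLR4 co-receptor Cd14 (0.16 ± 0.12), the NF-kB inhibitor Tnfaip3 (0.07 ± 0.08) and the glycolytic enzyme Aldoa (0.13 ± 0.08) were among the members that did not pass. The 3 HOXA and MEIS genes, 2 mast cell genes and 3 stromal genes measured included 0 calls.

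In all, edgeR called 127 of 11264 genes with LPS, 113 higher and 14 lower in KO, a balance that shifted to 359 higher and 186 lower without WT replicate 1, and 56 of them changed at least 2-fold (54 higher, 2 lower). DESeq2 called 265 and limma-voom 125. Leaving out 1 library moved the count to 545 (WT replicate 1), 129 (WT replicate 2), 20 (WT replicate 3), 55 (KO replicate 1), 61 (KO replicate 2) and 17 (KO replicate 3). In each of these 6 fits, Mir5107, Slamf1, Ch25h, B3gnt7, Lyz2, Ciita, Mmp13, Fn1 and Acp5 passed, and Steap4, Car2 and H2-Aa passed in 5. Il10, Ier3 and Cd24a passed in 4, Cxcl3 in 3, Tox2, Fblim1, Il12a, Ccl24 and Timp1 in 2, and Dipk2a, Arap2, Dapk1, Elovl6, Ifi44, Clec10a, H2-Eb1, Mmp8, Lck, Ppbp and Vcan in 1.

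**Figure D2:**
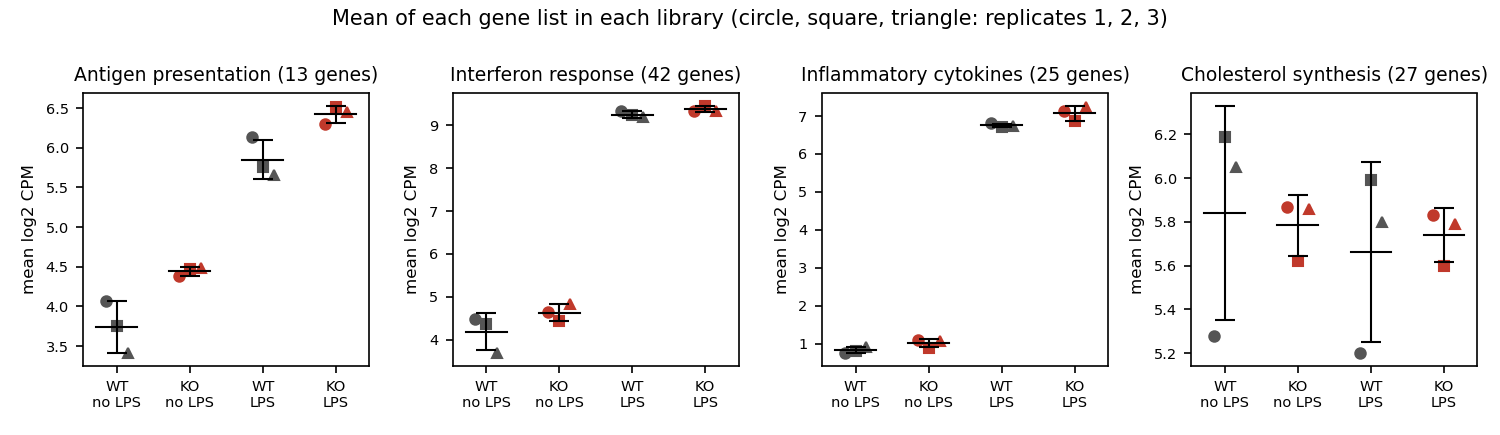
Mean log2 CPM (vertical axes, not from 0) of the genes of 4 lists in the 12 libraries, with WT in grey and KO in red, a symbol per replicate, a bar for the mean and whiskers for the SD of 3 libraries. Untreated KO libraries lie at 4.38 to 4.48 for antigen presentation, above WT at 3.41 to 4.07, while for cholesterol synthesis WT replicate 1 lies lowest, at 5.28 untreated and 5.20 with LPS.

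The LPS response was measured next, as LPS against no treatment in each genotype, on a common fit of 11984 genes. LPS raised cytokine, chemokine and interferon genes in WT and in KO. Cxcl10, a chemokine of interferon signalling, rose by 10.72 ± 0.15 in WT and 10.19 ± 0.14 in KO, Ccl5 by 9.39 ± 0.18 and 8.92 ± 0.17, and Ptgs2, the inducible enzyme of prostaglandin synthesis, by 9.24 ± 0.21 and 9.71 ± 0.21 on the log2 scale. Of genes near silence in untreated WT, Il12b had 3 reads untreated and 8988 with LPS, a 4505-fold rise in CPM (95% interval 1541 to 21850), Il6 rose 4488-fold (1242 to 37070) and Nos2, the nitric oxide synthase, 3532-fold (1860 to 7726). In KO, Il6 rose 2620-fold (1122 to 8069), and Sele, an adhesion molecule with 0 untreated reads, rose at least 410-fold. Among the largest decreases were Cnr2, a cannabinoid receptor (-5.69 ± 0.20 in WT and -5.80 ± 0.19 in KO), Irf2bp2, a co-repressor (-5.50 ± 0.14 and -5.54 ± 0.14), and Bmf, a promoter of apoptosis with 0 reads after LPS in WT, at least 47.9-fold lower. The adjusted p of every gene named in this paragraph was at most 1.24e-08, apart from Bmf (3.75e-06).

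All 42 interferon response genes rose in both genotypes, as did 24 of 25 inflammatory cytokines and 17 of 19 chemokines. Examples were the regulator Irf1 (5.56 ± 0.12 in WT, 5.10 ± 0.12 in KO) and the antiviral Mx2 (7.66 ± 0.19 and 7.23 ± 0.18). Negative feedback genes rose in 18 of 22 cases and fell in 3 in each genotype, with Socs3, an inhibitor of cytokine signalling, at 9.01 ± 0.18 and 8.77 ± 0.18 and the NF-kB inhibitor Nfkbia at 4.54 ± 0.10 and 4.87 ± 0.10. TLR4 and NF-kB pathway genes rose in 16 of 27 cases and fell in 4 in each genotype, with Nfkb1 at 2.72 ± 0.08 and 2.71 ± 0.08. Antigen presentation genes rose in 11 of 13 cases in each genotype, with the costimulatory receptor Cd40 at 7.60 ± 0.15 and 8.05 ± 0.15. Cell cycle genes fell in 28 of 42 cases in WT and 26 in KO and rose in 3, with the mitotic kinesin Kif23 at -2.04 ± 0.10 and -2.00 ± 0.10 and the arrest gene Cdkn1a at 2.71 ± 0.09 and 2.83 ± 0.09. Macrophage identity genes rose in 16 of 25 cases and fell in 5 in each genotype, with Irf8 higher (3.24 ± 0.10 and 3.14 ± 0.10) and the myeloid factor Cebpa (-4.91 ± 0.18 and -5.43 ± 0.18) lower. Adjusted over the list alone, all 25 cytokines rose in both genotypes and 12 antigen presentation genes in KO.

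Camera called 8 of 24 lists in WT. The adjusted p was 1.2e-25 for the interferon response (adjusted p = 0.157 with an estimated correlation), 2.91e-08 for negative feedback (adjusted p = 0.0757 with an estimated correlation), 0.00163 for the TLR4 pathway (adjusted p = 0.0757 with an estimated correlation), 3.04e-05 for antigen presentation (adjusted p = 0.265 with an estimated correlation), 3.05e-04 for the cell cycle and 0.045 for macrophage identity (adjusted p = 0.593 with an estimated correlation, both). Cytokines (1.1e-16) and chemokines (2.89e-11) held with an estimated correlation, at adjusted p = 0.0125 and 0.026. In KO camera called 7 lists, with macrophage identity at 0.075: the interferon response at 3.99e-23 (adjusted p = 0.193 with an estimated correlation), negative feedback at 4e-08 (adjusted p = 0.0814 with an estimated correlation), the TLR4 pathway at 0.00257 (adjusted p = 0.0898 with an estimated correlation), antigen presentation at 2.34e-04 (adjusted p = 0.316 with an estimated correlation), the cell cycle at 4.39e-04 (adjusted p = 0.598 with an estimated correlation), and cytokines (6.91e-16) and chemokines (6.42e-11), which held at adjusted p = 0.0147 and 0.0287. With the paired libraries as blocks within genotype, glycolysis passed as higher (0.0493 in WT, 0.0271 in KO), fatty acid synthesis as lower (0.0228 and 0.0255), and macrophage identity passed in KO too (0.0162). These did not pass with an estimated correlation (adjusted p = 0.591 and 0.532 for glycolysis, 0.375 and 0.423 for fatty acid synthesis, 0.276 for macrophage identity in KO). With the blocks and an estimated correlation, cytokines had an adjusted p of 0.0485 in WT and 0.0534 in KO, and chemokines of 0.089 and 0.094. The WT call of macrophage identity was lost without untreated WT replicate 2 (0.0695) or 3 (0.0628) or LPS-treated WT replicate 1 (0.0999). Glycolysis passed without untreated WT replicate 2 (0.0342) or 3 (0.0276) in WT, and without untreated KO replicate 2 (0.0478) or 3 (0.0461) or LPS-treated KO replicate 1 (0.0402) in KO. Fatty acid synthesis passed without untreated WT replicate 1 in WT (0.0226) and without LPS-treated KO replicate 1 in KO (0.0479). With an estimated correlation, these gained calls had adjusted p of at least 0.522 in WT and 0.599 in KO.

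Lipid genes responded to LPS in both directions. Of 27 cholesterol synthesis genes, 2 rose and 6 fell in WT and 3 rose and 5 fell in KO (list adjusted p = 0.573 and 0.914), with Dhcr7, the last enzyme of the pathway, at -1.08 ± 0.20 and -1.03 ± 0.20. Of 21 fatty acid synthesis genes, 2 rose and 8 fell in each genotype (0.0689 and 0.0785), with the acyl-CoA synthetase Acsl1 at 1.94 ± 0.10 and 2.11 ± 0.10 and the phosphatidate phosphatase Lpin1 at -3.69 ± 0.20 and -4.28 ± 0.20. The scavenger receptor Msr1 rose (1.40 ± 0.08 and 1.63 ± 0.08), and the lipid-sensing receptor Pparg (-2.12 ± 0.12 and -2.25 ± 0.12) and the LXR target Arl4c (-2.78 ± 0.19 and -3.18 ± 0.19) fell. Dot1l fell by 0.63 ± 0.11 in WT (adjusted p = 3e-04) and by 0.37 ± 0.11 in KO (adjusted p = 0.0107). The glycolytic enzyme Hk2 (2.37 ± 0.09 and 2.48 ± 0.09), the matrix gene Mmp13 (5.36 ± 0.13 and 5.24 ± 0.13), and the monocyte gene Vcan (6.97 ± 0.16 and 6.70 ± 0.15) rose. The lists without a call, which besides these hold LXR targets, lipid uptake, fatty acid oxidation, alternative activation, DOT1L partners, ATF4, NRF2 and early stress, and neutrophil, dendritic cell and osteoclast markers, had adjusted p between 0.0628 and 0.928 in WT and between 0.0636 and 0.986 in KO. The median and the direction of the test differed for LXR targets in WT (0.08, lower), lipid uptake in KO (-0.01, higher) and early stress in WT and KO (-0.30 and -0.41, higher).

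In total, edgeR called 6876 genes in WT (57.4%), 3309 higher and 3567 lower, and 7333 in KO (61.2%), 3633 higher and 3700 lower. Of these, 3110 and 3283 changed at least 2-fold. The balance of directions depends on scaling: higher genes made up 48.1% of calls in WT and 49.5% in KO with TMM, 31.7% in both with upper-quartile factors, and 18.4% and 18.6% on the authors' RPKM. The median log2 fold change of all genes was -0.05 in WT and -0.02 in KO with TMM, and -0.013 and -0.012 with DESeq2 size factors. It was -0.28 and -0.29 with upper-quartile factors and -0.53 and -0.54 on RPKM. Upper-quartile factors and RPKM thus moved values downward, so rises smaller than these shifts have no fixed direction.

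Whether the LPS response itself differed between genotypes was tested by the interaction. Of 42 interferon response genes, 38 had a negative difference, with a median of -0.31 on the log2 scale and 0 called (list adjusted p = 2.85e-11, and adjusted p = 0.881 with an estimated correlation). The median was -0.06, with 15 of 42 positive, without untreated WT replicate 3, and -0.56 without WT replicate 1. Their most abundant member, the antiviral Rsad2, had a difference of -0.44 ± 0.27. LXR targets were negative in 12 of 13, with a median of -0.07 (0.0372, and adjusted p = 0.881 with an estimated correlation) and Apoe at -0.13 ± 0.34. That median ran from -0.22 without untreated WT replicate 1 to 0.03, with 8 of 13 positive, without LPS-treated WT replicate 1. It was -0.13 to -0.16 without any of 5 others, untreated KO replicates 1 and 3, LPS-treated WT replicates 2 and 3 and LPS-treated KO replicate 2. Among single genes, Cxcl10 (-0.54 ± 0.16), Tnfaip3 (0.56 ± 0.17) and Cd40 (0.45 ± 0.18) missed the threshold, each with an adjusted p of 1, as did Dot1l (0.26 ± 0.16).

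Camera called these 2 of 24 lists, both as lower, at the preset correlation and 0 with an estimated correlation. The interferon call was lost without untreated WT replicate 3 (adjusted p = 0.25, range over the 12 fits without 1 library 6.16e-19 to 0.25), the library with the lowest interferon genes before LPS. The call of LXR targets was lost without untreated WT replicate 2 (0.221) or 3 (0.25), untreated KO replicate 2 (0.33), LPS-treated WT replicate 1 (0.544), or LPS-treated KO replicate 1 (0.145) or 3 (0.101). With the paired libraries as blocks within genotype, 4 lists passed: the interferon response (2.32e-14), LXR targets (2.68e-04) and lipid uptake (0.037) as lower, and cholesterol synthesis as higher (0.0033, against 0.499 unblocked). With an estimated correlation none of the 4 did (adjusted p = 0.716 for the interferon response and cholesterol synthesis, 0.262 for LXR targets and 0.599 for lipid uptake). The other 22 unblocked lists had adjusted p of 0.122 or more. Without untreated WT replicate 1, 8 of these passed: cholesterol synthesis (2.59e-06), chemokines (0.0144), negative feedback (0.0123), cell cycle (0.0256) and glycolysis (0.0084) as higher, and lipid uptake (0.04), macrophage identity (0.0123) and antigen presentation (0.04) as lower. Others passed without LPS-treated WT replicate 1 (negative feedback, 0.00144), WT replicate 2 (cholesterol synthesis, 0.0147) or KO replicate 2 (cytokines, macrophage identity and matrix remodelling, each 0.0478). With an estimated correlation, the 13 calls gained without 1 library had adjusted p of at least 0.453.

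No gene of 11984 passed the interaction in edgeR, where 288 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 as well. These fits left the pairs out of account. With the paired libraries as blocks within genotype, edgeR called 0 too. A call in 1 genotype and not in the other is therefore not shown to be a difference between genotypes for any gene. Without both WT replicate 1 libraries, a fit added after the data had been seen, edgeR called 24 genes. No gene was called in both genotype comparisons, since the untreated cells gave 0 calls.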

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

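Apart from the counts of other splits, the tests of this part (on labels, exons, cell types, Cre and single libraries) were chosen after the results they bear on had been seen.

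At the preset correlation, camera on the interaction called 2 lists: the interferon response genes (adjusted p = 2.85e-11) and the LXR targets (adjusted p = 0.0372), both with a lower LPS change in KO. Neither passed with an estimated correlation (adjusted p = 0.881 for both). The interferon call was kept in 11 of 12 fits without 1 library and the LXR call in 6 of 12. After LPS the interferon genes were not lower in KO, with a mean log2 CPM of 9.34 to 9.45 against 9.18 to 9.33 in WT.

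Dot1l reads were not lower in KO by the test, at a log2 fold change of -0.15 ± 0.13 without LPS. Exchanged labels are argued against by Lyz2, of which the highest KO library had 0.537 of the lowest WT library in the condition where the 2 came closest. Reads of exons that the deletion leaves remain a candidate explanation, which the value of -0.15 cannot decide because it covers the whole transcript and no counts per exon exist in the tables. A lower amount of DOT1L protein or of its histone mark was not measured here. Without untreated WT replicate 1, the value became -0.28 and passed (adjusted p = 0.0244).

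The MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were together higher in KO libraries, with a ratio of pooled reads of 2.15 without LPS (95% counting interval 2.09 to 2.20) and 2.11 with LPS (2.07 to 2.16). Single libraries had 155.2 to 308.9 CPM in WT and 415.3 to 477.1 CPM in KO without LPS. With LPS they had 295.3 to 614.8 CPM in WT and 769.1 to 877.8 CPM in KO. The intervals of this paragraph leave out that spread between libraries. More B lymphocytes are argued against, since 5 genes of these cells together reached 0.350 CPM in KO, 0.106% of the MHC class II excess of 328.9 CPM. This rests on their low level alone. Their KO to WT ratio, 1.17 over both conditions (0.626 to 2.22, 19 reads in WT and 27 in KO), decides nothing. It was 1.91 without LPS (0.830 to 4.76) and 0.542 with LPS (0.175 to 1.58). Dendritic cells were judged by such a ratio instead, so the criteria differ. More dendritic cells remain a candidate explanation, as their markers, less Itgax and Cd24a, which macrophages express, had a KO to WT ratio of 1.63 over both conditions (1.41 to 1.90, 275 reads in WT and 546 in KO), 1.46 without LPS (1.14 to 1.88) and 1.67 with LPS (1.39 to 2.01). The criteria for both cell types were rewritten after a first version had been read, and by that first version, which required the marker ratio to reach the MHC class II ratio, dendritic cells would have been argued against because these upper bounds lie below the MHC class II ratios. Cre at the Lyz2 locus cannot be told apart from the loss of DOT1L. Lyz2 itself was lower in KO than in WT, at a log2 fold change of -1.17 among LPS-treated cells. The labels name no group with Cre and an intact Dot1l.

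The interferon response list passed as higher in KO before LPS and as lower in the interaction at the preset correlation, with 0 genes called in either and with neither passed with an estimated correlation (adjusted p = 0.621 and 0.881). Untreated WT replicate 3 had the lowest mean log2 CPM of the list (3.69, against 4.37 to 4.83 in the other 5 untreated libraries). Without that library the difference before LPS passed at the preset correlation (adjusted p = 7.96e-04, with 32 of 41 genes higher and a median of 0.24 in place of 0.44), while with an estimated correlation it did not pass without it either (adjusted p = 0.786), so that library's part in it stays undecided. It is a candidate explanation for the difference in LPS response, since the list did not pass without it (adjusted p = 0.25, range over the 12 fits without 1 library 6.16e-19 to 0.25). Differences between single animals stay open beside the loss of DOT1L: 2 of the 10 splits of the untreated libraries gave a mean difference as large, the real one with 0.488 and the highest other with 0.524.

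Splits of the same libraries into 3 and 3 number 10, too few for a share under 0.05. Every other split also puts libraries of both real groups on each side. A real difference then widens the spread within the sides and can hold the count at 0. The 0 genes called in other splits therefore do not show what chance alone gives. The real split called 0 genes for KO without LPS (highest other 0, so all 10 as many; 841 genes at an unadjusted p under 0.05 in edgeR, DESeq2 49, limma-voom 0), 127 for KO with LPS (highest other 0, 1 split as many), 6876 and 7333 for LPS in WT and KO (highest other 0, 1 split as many in each; the other splits were 3 that part all 3 pairs, as the real one does, and 6 that part 1 pair, and all 9 called 0) and 0 for the interaction (highest other 0, all 10 as many; 288 at an unadjusted p under 0.05, DESeq2 0, limma-voom 0). Lists called were 5 for KO without LPS (highest other 11, 6 splits as many), 9 for KO with LPS (highest other 12, 5 splits), 8 and 7 for LPS in WT and KO (highest other 12 and 12, 6 splits each; 8 and 7 among the 3 others that part all 3 pairs) and 2 for the interaction (highest other 4, 4 splits). Genes called in both KO comparisons were 0 (highest other 0, all 10 as many). At an unadjusted p under 0.05, 2 of the other groupings without LPS gave more genes than the 841 of the real one, 1641 with WT replicate 1 beside KO replicates 1 and 2 and 1055 with KO replicate 1 beside WT replicates 2 and 3.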

How the results depend on the processing

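Sex as a covariate, female libraries only and fits without both WT replicate 1 libraries were chosen after the data had been seen; the cause of the changes below was not tested, except that a stricter threshold or a minimum fold change calls fewer genes by construction. For KO without LPS (0 genes in edgeR, 841 at an unadjusted p under 0.05, limma-voom 0), the count was 1 with upper-quartile factors, 49 with DESeq2, 9 without a filter, 27 with all 12 libraries in 1 fit and 553 with these less both WT replicate 1 libraries, and it ran from 0 to 749 without 1 library (749 without untreated WT replicate 1). For KO with LPS (127 genes), it was 265 with DESeq2, 276 without a filter, 42 at a threshold of 0.01, 56 at a log2 fold change of at least 1, 76 on RPKM, 47 with the replicate number as a block, 69 with sex as a covariate, 669 in the 12-library fit less both WT replicate 1 libraries and 17 in female libraries, and it ran from 17 to 545 without 1 library (545 without LPS-treated WT replicate 1, 20 without WT replicate 3, and 55, 61 and 17 without KO replicates 1, 2 and 3). For LPS, 3110 genes in WT and 3283 in KO had a log2 fold change of at least 1, and counts without 1 library ran from 6320 to 7418 and from 6689 to 6779. The interaction (0 genes in edgeR, 288 at an unadjusted p under 0.05, DESeq2 0, limma-voom 0) gave 24 genes without both WT replicate 1 libraries and 0 to 0 without any 1 library.

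Lists called for KO without LPS (5) were 0 with an estimated correlation, 0 with fry and 8 in female libraries, and 4 to 12 without 1 library. For KO with LPS (9) they were 0 with an estimated correlation, 2 with fry, 8 in female libraries and 7 to 14 without 1 library. For LPS in WT (8) they were 2 with an estimated correlation, 20 with fry and 7 to 9 without 1 library, and in KO (7) 2, 21 and 7 to 9. For the interaction (2) they were 0 with an estimated correlation, 0 with fry, 1 without a filter, 4 with blocks within genotype, 7 without both WT replicate 1 libraries and 0 to 10 without 1 library. Genes called in both KO comparisons (0) were 17 with 12 libraries, 30 with DESeq2 and 0 to 42 without 1 library. Dot1l differed by -0.276 to -0.084 untreated and by 0.024 to 0.125 with LPS without 1 library.

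No named gene turned direction while called. Over the named genes and alternatives, the value stayed on its side of the threshold, called or not, in 317 cases for KO with LPS (104 calls lost, 2 gained), 815 for LPS in WT (13 lost) and 826 for LPS in KO (2 lost). For KO without LPS and for the interaction, which have no called gene, 252 and 450 cases stayed uncalled and 9 calls were gained, all 9 for KO without LPS. Across genotypes, libraries share only a number: their deviations correlated at 0.05, 0.18 and 0.26 untreated and -0.03, 0.19 and 0.12 with LPS, and not every library correlated best with its own number. With that number as a block, edgeR called 0, 47, 7051, 7527 and 0 genes in the 5 comparisons, and 8156 and 8701 for LPS with the pairs within genotype. Thinned to the smallest library, KO with LPS gave 109 genes and LPS 6648 in WT and 6951 in KO. Genes near 3 counts, at 0.222 to 0.347 CPM, were not tested apart.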

Other observations

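The tests of this part, and the genes it names, were chosen after the results had been seen.

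When all 12 libraries were fitted together, edgeR called 27 genes for KO against WT in untreated cells, 23 higher and 4 lower, of which Gm4070 and Gvin1 have the same counts in all libraries and are not separate findings. That fit takes the 12 libraries as independent, although the untreated and LPS-treated ones were taken as paired within a genotype, and the 27 rest on that. Among the higher ones were the collagenase Mmp13 (log2 fold change 1.18 ± 0.12), the fibronectin gene Fn1 (1.14 ± 0.16) and the protease Htra1 (1.79 ± 0.32). Higher too were the class II genes H2-Aa (1.13 ± 0.18) and Ciita (1.20 ± 0.22), the interleukin receptor Il1r1 (1.59 ± 0.26), the prostaglandin synthase Ptgs1 (0.75 ± 0.11), the growth factor Bmp2 (1.35 ± 0.25) and the kinesin Kif1a (1.89 ± 0.29). The 4 lower ones were Lyz2 (-1.18 ± 0.12), the elongation factor Ell2 (-0.49 ± 0.08), the phosphodiesterase Pde8a (-0.50 ± 0.09) and the phosphatase Dusp7 (-0.43 ± 0.07). Of the 27, 17 were also called with LPS in the same 12-library fit and in the same direction, 14 higher and 3 lower, on the same assumption. The other groupings of the same 6 animals had 0 calls in either condition in that fit, so they had none to share and say nothing of the sharing. With the 6 untreated libraries alone edgeR called 0 of them (841 genes at an unadjusted p under 0.05, DESeq2 49, limma-voom 0).

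Of the 88 genes called with LPS and tested in both KO comparisons, 84 had the same sign, but the 88 genes of smallest p in the other groupings of these animals had 69 to 87 with the same sign, so the count says nothing of the genotype. Across all genes tested in both, the 2 sets of differences correlated at r = 0.594, and other groupings of the same animals into 3 and 3 gave 0.315 to 0.538. The libraries of both conditions were taken to come from the same animals, and the 10 groupings are too few for a share under 0.05.

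A hypothesis was that genes higher in KO with LPS are mostly genes that LPS raises in WT. Of the 112 such genes tested for LPS, 88 (78.6%) were raised by LPS in WT, against 29.4% of all genes. A high level after LPS, whatever the genotype, is argued against as the whole reason: in 10000 random lists matched on mean level with LPS, the mean was 30.3 raised genes and the highest 46. Of the 14 genes lower in KO with LPS, LPS raised 2 and lowered 11 in WT. The interaction called 0 genes, so these counts do not show that LPS changed any gene more in KO than in WT. Whether LPS-raised genes also vary more between animals was not tested, and the loss of DOT1L was not separated from Cre.

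Dot1l and Lyz2 both lie on chromosome 10. With these 2 left out, 3 genes within 5 Mb of either were called for KO with LPS where the share of all genes gives 2.10, and on the whole chromosome 5 were called where it gives 6.08.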
